A study of Macaca mulatta with 9 samples.

How the data were processed

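Total RNA from the prostates of 9 rhesus monkey (Macaca mulatta) offspring was measured on 9 Agilent 1-colour arrays, 1 per animal. The dams had received vehicle, 30 or 300 ng/kg TCDD under the skin on gestation day 20, and then 5% of that dose at intervals of 30 days, the last on day 90 after birth. Per the labels, necropsy came 7 years after exposure and 0.5 ug of RNA was labelled with Cy3. Samples were grouped by the dose in their labels, 3 offspring per group, and are named here by dose and replicate number.

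Per the file headers, the authors extracted the array images with Agilent Feature Extraction 9.5.1.1 (9.5 in the labels). The deposited processed signal is an intensity on a linear scale, background-subtracted and detrended by that program for each array on its own, with no normalization between arrays. The median spot and local background signals in the same deposited files are intensity values as well. The authors' deposited table gives, for 1502 probes, a fold as a ratio of at least 1 with the direction beside it, and group means as log2 values before the authors' normalization. Its means after normalization were not used here, and the method of that normalization is not given in the sources used here. For 1479 of these probes the deposited raw means equalled the mean log2 of the processed signal with values under 5 set to 5, within 0.01. The authors' table states as its criteria a 1-way analysis of variance p of at most 0.05 and a fold of at least 1.5.

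The array files name no genes. A gene symbol is carried by 1109 of the 1502 probes that the authors list (1076 symbols, of which 970 were on tested probes), and 14162 of the tested probes have none. Of the symbols, 867 (80.6%) were found in the macaque reference table, while only 8 array accessions were. Most probe descriptions in the authors' table name human transcripts. Genes without a symbol there, among them CYP1A1, CYP1B1, AHRR and TGFB1, were not analysed here, and the table's 9 columns of per-sample flags were not used here.

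Each of 20217 probes had 2 spots. Spots flagged as outliers by the extraction program were left out unless both spots of a probe were flagged. The processed signal was then averaged over the spots of a probe. This mean was taken relative to the 75th percentile of its array, floored at 5 signal units of the dimmest array, and put on the log2 scale. The floor lay at -6.10 on that scale. The floor was set after the files were opened. All 10 saturated spots belonged to 1 probe of KLK3, on 6 arrays. The 15160 probes that the extraction program marked well above background on all arrays of at least 1 group were tested, and 5057 were not. The number of arrays limits the precision: the median residual SD per probe was 0.400 on the log2 scale, with 6 residual and 2.99 prior degrees of freedom.

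All 9 arrays entered 1 fit of limma 3.58.1 (R 4.3.3, statmod 1.5.0, data.table version 1.17.8) with group as the only term and moderated variances. It gave 30 ng/kg minus vehicle, 300 ng/kg minus vehicle, 300 minus 30 ng/kg, and the mean of both exposed groups minus vehicle. Calls needed a Benjamini-Hochberg adjusted p under 0.05 over all tested probes, 2-sided. Gene lists, 32 with 586 members, were set against these comparisons by camera with a preset correlation of 0.01 where at least 5 members were tested, on the brightest probe per gene. The lists matched 43 distinct genes with at most 4 per list, and the background of the list tests was the named genes alone. The correlation of both dose effects was set beside 100 simulations of unchanged groups, with each probe drawn independently. A gene was named if it was among the 10 higher or the 10 lower genes with the smallest p of a comparison (5 each for the exposed mean), among up to 4 members of a described list, or among 19 genes written down in advance, of which KLK3, MSMB, COL1A1 and MMP2 were measured. Some genes that met these conditions are not reported here. A list was described in a comparison if at least 1 member had an unadjusted p under 0.05, a limit chosen after the results were seen. A fold is given as a lower bound where 1 group had no array well above background.

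The groups, the comparisons and their tests, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The alternatives set in advance were normexp background correction, quantile and median scaling, no filter, a filter on all 9 arrays, a fit on the compared groups alone, slide as a fixed or a random block, arrays of a single slide, replicate number as a block, array weights, a trended robust prior, each array left out, an unadjusted p with a fold of at least 2, other list tests and the mean of a gene's probes. normexp was planned on the mean signal, a column the files lack, and was run on the median signal with an offset of 50. Added later were a floor of 1 unit, a floor before scaling, brightness as a covariate, lists of at least 3 genes, the unfiltered list test with an estimated correlation and the authors' own criteria. Slides were read from the array identifiers.

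The limma fit was tested on simulated log2 values with each probe's residual SD over all groups, for 300 ng/kg against vehicle. Scaling, floor, averaging of spots and the filter were not part of this test. Of 15160 probes, 200 were changed, 50 per fold size, in 10 runs. Recovery was 1.2% at 1.5-fold, 7.8% at 2-fold, 59.4% at 4-fold and 81.6% at 8-fold, and 46 unchanged probes were called over the 10 runs.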

Results

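The series asks what exposure to TCDD before birth and during nursing does to the prostate gland and its stroma in grown rhesus monkeys. TCDD is a persistent dioxin that binds the aryl hydrocarbon receptor. The dams received vehicle, 30 or 300 ng/kg TCDD, and each of 3 offspring per group gave 1 prostate array, 9 arrays in all. The 75th percentile of signal averaged 832 ± 341 intensity units (SD, n = 3) in the vehicle group, 684 ± 577 at 30 ng/kg and 1741 ± 575 at 300 ng/kg. The share of spots well above background was 73.4% ± 6.32 in vehicle, 70.0% ± 7.95 at 30 ng/kg and 81.4% ± 2.29 at 300 ng/kg. Across probes, which are not independent replicates, arrays of the same group correlated at 0.945 to 0.975 and arrays of different groups at 0.884 to 0.984. The arrays lay on 3 slides, and no slide held both vehicle and 300 ng/kg arrays. Slide 3 held all 3 arrays of 300 ng/kg beside 1 array of 30 ng/kg, and slide 2 held 1 vehicle array beside 2 arrays of 30 ng/kg. Slide 1 held only 2 vehicle arrays, which add nothing to a comparison once slide is a fixed block. Such a fit sets 300 ng/kg against 1 vehicle array, by way of the 30 ng/kg arrays on slides 2 and 3. Its differences between 30 ng/kg and vehicle are those within slide 2, and between the doses those within slide 3.

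The first principal component held 43.9% of the variance after scaling and followed the brightness of the arrays. Over the 9 arrays, its score and the log2 of the 75th percentile had a Pearson r of 0.893 (2-sided exact permutation p = 0.00135) and a Spearman rho of 0.883 (exact permutation p = 0.00308). This was the only relation tested across arrays. Without the 2 arrays farthest from the median brightness, both of 30 ng/kg, r was 0.836 over the 7 left. Within slide 3 (4 arrays) r was 0.954 and within slide 2 (3 arrays) 0.799, and slide 1 held too few arrays for a value. Within the groups r was 0.998 at 30 ng/kg, 0.751 at 300 ng/kg and 0.521 in vehicle, with 3 arrays in each.

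**Figure D1:**
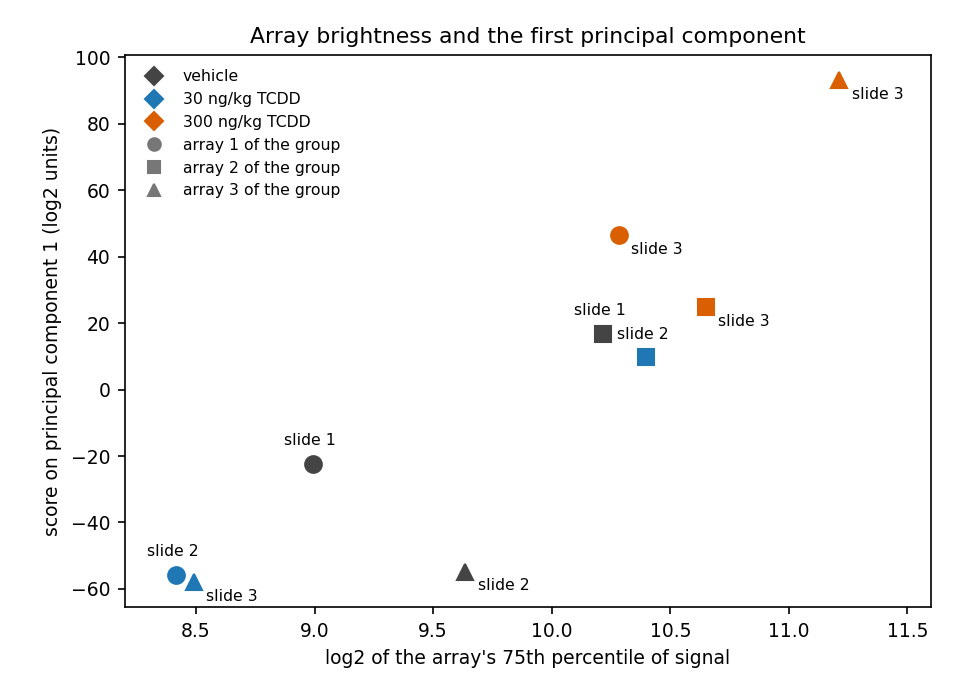
Score on the first principal component against the log2 of each array's 75th percentile of signal, 1 point per array, with the colour for the dose, the shape for the replicate and the slide written beside it. The 3 arrays of 300 ng/kg lie on slide 3 and have the highest scores, and r over the 9 arrays was 0.893.

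In the prostates of the 300 ng/kg offspring, the 3 tested transcripts of the glandular secretions did not all go 1 way. TGM4, a transglutaminase of seminal plasma, had a log2 difference from vehicle of 8.87 ± 1.44 (SE of limma's fit, n = 3 per group). Its 300 ng/kg arrays read 6.81, 1.42 and 7.41 on the log2 scale relative to the 75th percentile of the array, against -3.89, -4.55 and -2.54 in vehicle. The brightest probe of KLK3, which encodes prostate-specific antigen, had saturated spots on 6 of the 9 arrays, so its scaled values follow array brightness and no size is given from it. The other KLK3 probe had 0 saturated spots and stood at -1.47 ± 0.59. MSMB, another abundant secreted protein of the gland, stood at -0.73 ± 0.36, and its groups overlapped. The TGM4 and MSMB differences were 9.24 and -0.33 with slide as a fixed block. Among other epithelial genes, the hillock keratin KRT13 stood at 2.78 ± 0.67, with only 1 vehicle array well above background. The basal genes S100A2 and ITGB4 stood at 1.55 ± 0.57 and 0.21 ± 0.24, and neither had separate groups. CRABP2, which carries retinoic acid to its receptors, stood at 4.31 ± 1.24 and the retinol carrier RBP4 at 2.27 ± 0.64. CRABP2 read 2.16, -3.47 and 1.52 on the 300 ng/kg arrays, so replicate 2 lay far below the other two. GPX2, a glutathione peroxidase of epithelia, stood at 2.93 ± 0.62. Replicate 2 of 300 ng/kg by itself stood at 1.43 for GPX2, 0.89 for RBP4 and 0.07 for S100A2, each under the group mean. For KRT13 it was replicate 1 that read lower than replicate 2.

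**Figure D2:**
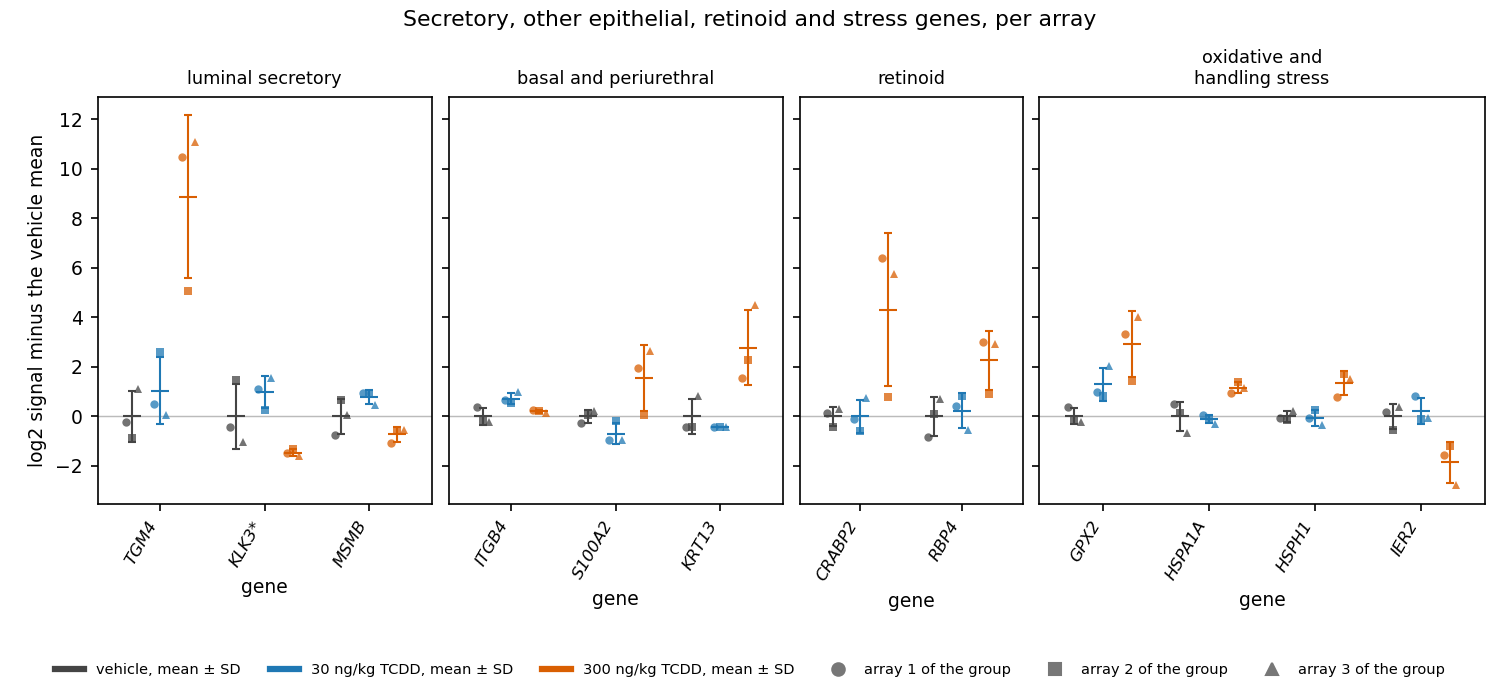
Log2 signal minus the vehicle mean for secretory, basal and periurethral, retinoid and stress genes, with 1 point per array, the shape for the replicate, and bars for the group mean ± SD of 3 arrays. TGM4 has a difference of 8.87 at 300 ng/kg, KLK3 (asterisk) is drawn from its probe without saturated spots and has one of -1.47, and in the TGM4 and CRABP2 columns replicate 2 of 300 ng/kg lies nearest to vehicle of its group.

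The tested genes of matrix assembly and of the response to TGF-beta, the main inducer of fibrosis, were mostly above vehicle at 300 ng/kg. Few listed genes could be tested: 4 of 21 for TGF-beta signalling, 4 of 25 for matrix crosslinking, 4 of 27 for collagen and matrix, and 3 of 22 for development. All had been picked by the authors' table on these same arrays, so members without a difference between groups could not appear. The TGF-beta signalling genes LTBP2, SMAD7 and TGFBI were higher, with each of the other scalings too, and stood at 1.00 ± 0.31, 0.76 ± 0.26 and 1.05 ± 0.41 (log2 ± SE, n = 3 per group). All 4 tested genes of matrix crosslinking and turnover were higher with each scaling as well. These were the collagen prolyl hydroxylase P4HA2 (1.68 ± 0.40), the procollagen protease ADAMTS2 (1.39 ± 0.37), the gelatinase MMP2 (0.90 ± 0.29) and the collagen chaperone SERPINH1 (0.74 ± 0.26). Collagen genes went both ways: COL1A1 stood at 1.54 ± 0.41, COL1A2 at 0.75 ± 0.29, COL5A2 at 0.48 ± 0.22 and COL6A2 at -1.61 ± 0.48. The developmental regulators GREM1, a BMP antagonist, WNT5A and SFRP1 stood at 3.26 ± 0.73, 1.24 ± 0.32 and 1.16 ± 0.41, and kept that side with each scaling. With slide as a fixed block, P4HA2 stood at 3.30, COL1A1 at 2.04, GREM1 at 2.97, TGFBI at 1.32, LTBP2 at 0.79 and SMAD7 at 0.28, and COL5A2 turned to -0.23.

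**Figure D3:**
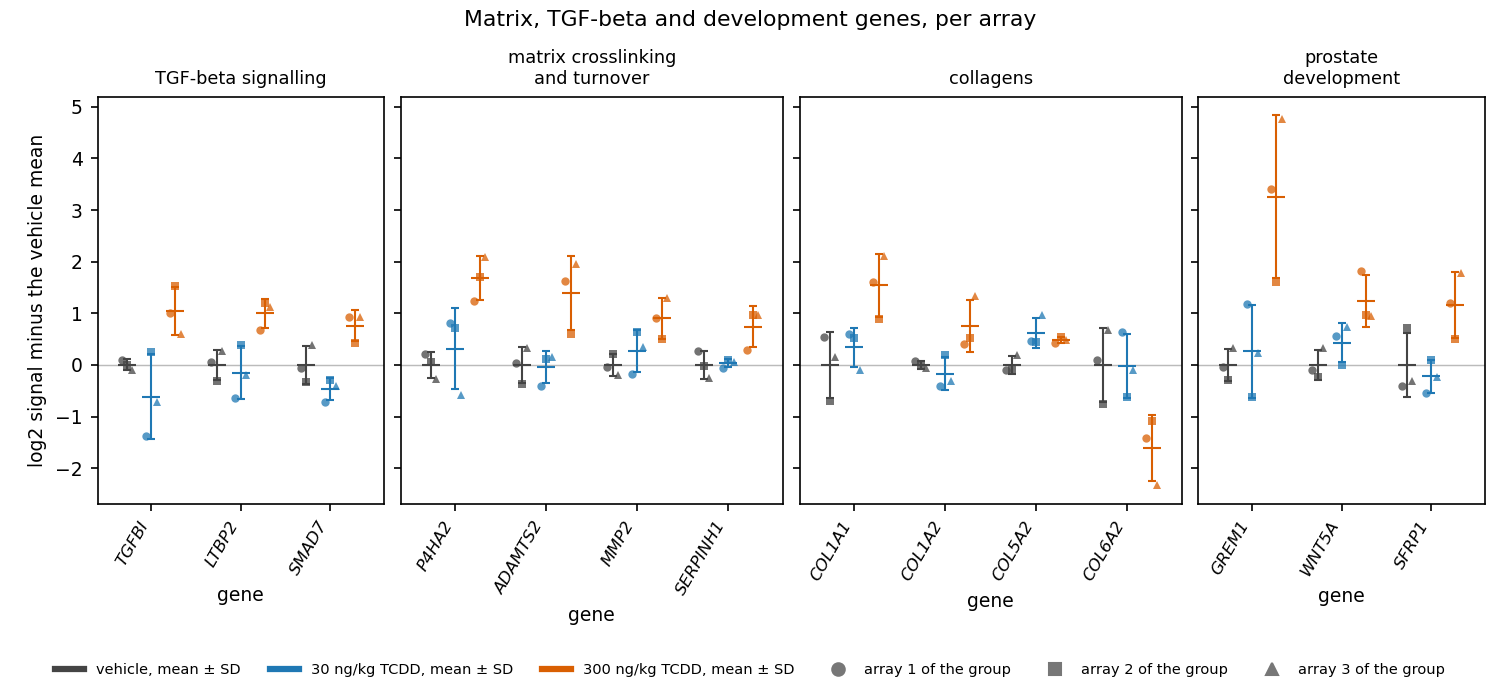
Log2 signal minus the vehicle mean for genes of TGF-beta signalling, matrix crosslinking, collagens and prostate development, with 1 point per array, the shape for the replicate, and bars for the group mean ± SD of 3 arrays. At 300 ng/kg the 3 TGF-beta genes have means above vehicle, COL1A1 stands at 1.54 and COL6A2 at -1.61.

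Further tested genes of the lists at 300 ng/kg covered contractile, matrix-boundary, immune and stress functions. The smooth muscle genes LMOD1 and TPM2 stood at -0.80 ± 0.28 and -0.73 ± 0.32, and the basement membrane laminins LAMA5 and LAMB2 at -0.65 ± 0.22 and -0.78 ± 0.34 (log2 ± SE, n = 3 per group). The heat shock genes HSPH1 and HSPA1A stood at 1.34 ± 0.29 and 1.16 ± 0.31, whereas the immediate early gene IER2 stood at -1.84 ± 0.46. Of 2 tested targets of the aryl hydrocarbon receptor, SLC7A5 stood at 0.94 ± 0.34 and ALDH1A3 at -0.63 ± 0.28. RELB, a receptor partner and NF-kappaB subunit, stood at -0.97 ± 0.26. The adipocyte lipase LPL stood at 1.24 ± 0.29, the plasma cell factor XBP1 at 1.39 ± 0.28 and the mast cell receptor FCER1A at 2.15 ± 0.51, with 1 vehicle array well above background. The glucocorticoid receptor gene NR3C1 stood at 0.64 ± 0.23 and the steroid sulfatase gene STS was at least 1.54-fold higher. The antigen-processing protease CTSS stood at 0.69 ± 0.25. With normexp background correction, which shifted the median of all probes by -0.22, CTSS turned to -0.16 and STS to -0.49; relative to that shift they stood at 0.06 and -0.27.

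Outside the lists, the named genes with the smallest p at 300 ng/kg included enzymes of lipids, matrix and DNA breakdown. The endothelial lipase LIPG was at least 5.44-fold higher, and the pantetheinase VNN2 at least 12.1-fold higher, both with no vehicle array well above background. The ubiquitin-like modifier UBD stood at 2.42 ± 0.34, the hyaluronan synthase HAS2 at 1.78 ± 0.27, the homeobox gene IRX4 at 2.21 ± 0.34 and the crystallin CRYAA at 3.35 ± 0.56 (log2 ± SE, n = 3 per group). HAS2 and CRYAA had 1 vehicle array well above background, so their sizes are limited by the floor. The annexin ANXA1, the chaperone DNAJA1 and the nuclease DNASE1L3 stood at 2.07 ± 0.34, 1.34 ± 0.22 and 2.60 ± 0.45. On the lower side, the muscle sarcoglycan SGCA stood at -1.74 ± 0.27, the neuropeptide NTS at -2.59 ± 0.56, the calcium pump ATP2B3 at -2.62 ± 0.54 and LIX1 at -2.40 ± 0.46. SLC12A3, EYA1, PAMCI, CPXM2, FARP1 and WNT5B stood between -2.05 and -1.25. With slide as a fixed block, UBD stood at 2.68, HAS2 at 2.08 and IRX4 at 2.02.

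None of these differences passed the test over all probes. limma called 0 of 15160 probes at an adjusted p under 0.05 between 300 ng/kg and vehicle, with a smallest adjusted p of 0.158. At an unadjusted p under 0.05 there were 2357 probes, 1119 higher and 1238 lower, where chance gives 758. With 1 array left out this count ranged from 997, without replicate 3 of 300 ng/kg, to 2860, without its replicate 2, and it was 1418 without replicate 1 of vehicle. Brightness as a covariate gave 1116, normexp 1246 (413 higher, 833 lower), median scaling 2391 (1283 and 1108), slide as a fixed block 2848 (544 and 2304) and array weights 4634, so neither the count nor its balance is settled. The p-values rest on 1 moderated spread per probe, pooled over the 3 groups of 3 animals and not taken from the compared groups alone. With 1 array per animal, that spread also holds differences in brightness and slide. The groups did not overlap at 3434 probes, 22.7% of those tested, where chance gives 10%. Without replicate 2 of 300 ng/kg, limma called 271 probes, and with array weights 198. In simulated data with each probe's residual SD over all groups, the fit recovered 7.8% of 2-fold, 59.4% of 4-fold and 81.6% of 8-fold changes. Its noise was independent between probes, so recovery on the real arrays may differ.

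Gene names came from the authors' table, whose probes were chosen on these same samples, so the list results are not independent evidence. Over all 15160 probes, 0 list genes passed in any comparison. For 300 ng/kg against vehicle, adjusted over the list alone, 4 of 4 genes passed for TGF-beta signalling, 4 of 4 for matrix crosslinking, 3 of 3 for prostate development and 3 of 4 for fibrillar collagen and matrix. It was 3 of 3 for immediate early and handling stress, 1 of 3 for luminal secretory genes (TGM4), and 1 of 2 for basal epithelium (S100A2). Both tested genes passed in each of the lists for smooth muscle, basement membrane, retinoid metabolism, adipocytes, steroid receptors and metabolism, and targets of the aryl hydrocarbon receptor. Of the lists with 1 tested gene, the components of the receptor pathway, oxidative stress, androgen-responsive genes, periurethral epithelium, B and plasma cells, mast cells, class II presentation and nerve each passed, and the interferon and endothelium lists did not. The gene of the androgen-responsive list is KLK3 by its saturated probe, so that pass is not read as a change. The secretory list holds the same probe. In a list with 1 tested gene, the adjusted p is the unadjusted p. Every tested list except interferon and endothelium had a gene that passed, which the choice of the names favours. Passing therefore sets no list apart. Epithelial junctions, T and NK lymphocytes, myeloid cells, cytokines, proliferation, seminal vesicle, urothelium, skeletal muscle and erythrocytes had no tested member and were not analysed here.

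No list reached the 5 tested genes that camera was set to need, so the planned list test had 0 lists to call in every comparison. Over the 6 lists with at least 3 genes, camera with its preset correlation gave TGF-beta signalling, matrix crosslinking and prostate development an adjusted p of 0.0628 each at 300 ng/kg against vehicle. Over the other settings this ranged from 0.0475 to 0.238 for TGF-beta, 0.0133 to 0.0993 for crosslinking and 0.0366 to 0.238 for development. With an estimated correlation the values were 0.320, 0.287 and 0.287. The rotation test fry, which asks only whether the genes of a set move on balance 1 way, gave 0.00980, 0.00584 and 0.00584, and 0.0389 for collagens and matrix, for which camera gave 0.495 and 0.543. All 3 list means stayed above 0 with slide as a fixed block, at 1.49 for crosslinking and 1.64 for development, but that fit rests on 1 vehicle array. The secretory list had a mean of 2.32, a median of -0.73 and an upward camera direction (adjusted p 0.929), so its summaries differ in sign.

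In the 30 ng/kg offspring, the genes with the smallest p were of many kinds and form no tested group. LPL, which releases fatty acids from lipoproteins, stood 1.52 ± 0.29 above vehicle on the log2 scale (SE, n = 3 per group), and the endothelial adhesion gene PECAM1 stood at 1.31 ± 0.29. UBD stood at 1.56 ± 0.34, the prekallikrein gene KLKB1 at 2.26 ± 0.43 with its other probe at 2.23, and the collagen COL22A1 at 2.37 ± 0.55. ST8SIA1, ALCAM, CNKSR1, ING4 and FNDC6 stood between 1.04 and 1.65. KLKB1 and ST8SIA1 had 1 vehicle array well above background. On the lower side, the extracellular protein MYOC stood at -1.70 ± 0.33, RELB at -1.02 ± 0.26, the neural adhesion gene LSAMP at -0.83 ± 0.19, the lens filament gene BFSP1 at -0.93 ± 0.24, RPS6KA2 at -0.89 ± 0.24 and COX11 at -0.99 ± 0.26. ADCYAP1, CBLNL1 and TMEM31 had no 30 ng/kg array well above background and were at least 1.67-, 1.43- and 1.36-fold lower. These 3 genes and COX11 turned upward with normexp, to values between 0.13 and 0.63 where the median of all probes moved by 0.29; relative to it, COX11 alone of the 4 stayed below 0, at -0.17. Within slide 2, from 1 vehicle array and 2 arrays of 30 ng/kg, LPL stood at 1.27, UBD at 1.54, PECAM1 at 1.27, MYOC at -1.84 and RELB at -0.70.

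**Figure D4:**
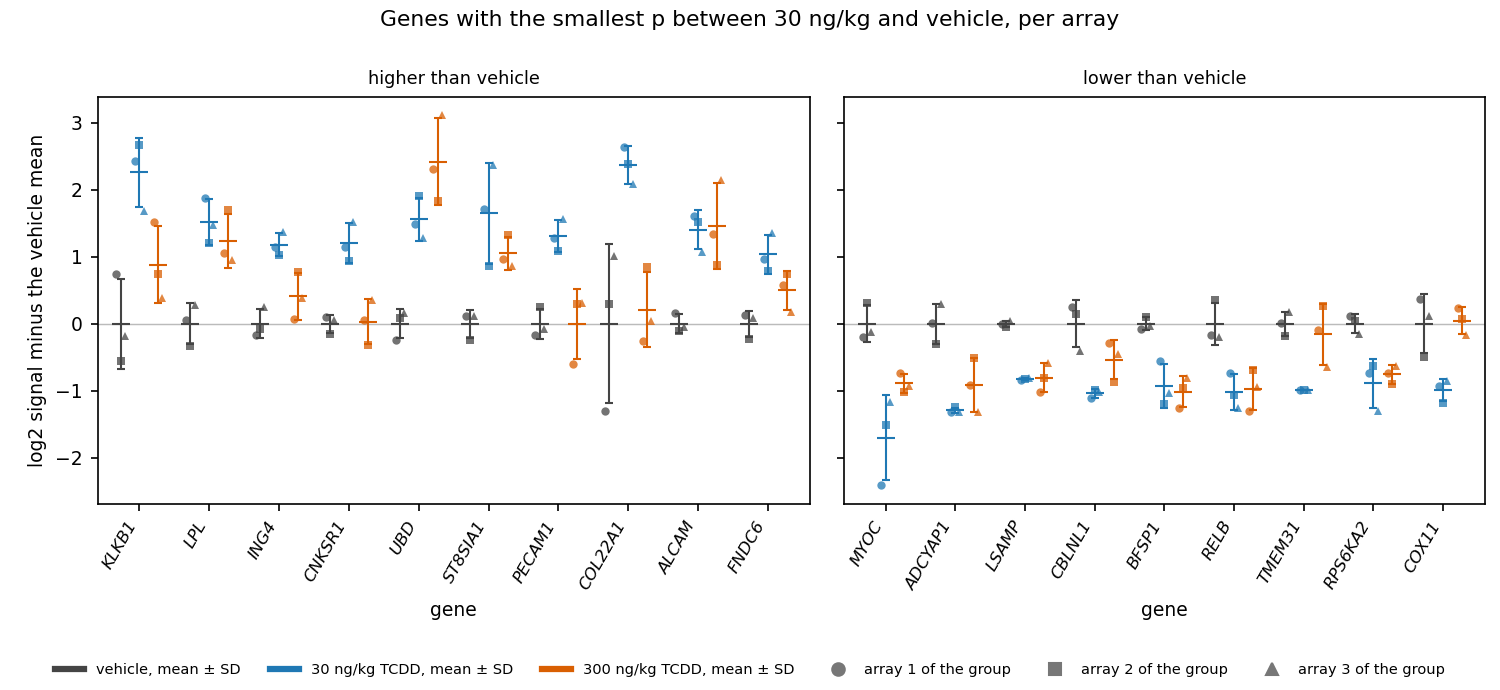
Log2 signal minus the vehicle mean for named genes with the smallest p between 30 ng/kg and vehicle, with 1 point per array, the shape for the replicate, and bars for the group mean ± SD of 3 arrays. LPL and UBD lie above vehicle at both doses, whereas PECAM1 stands at 1.31 at 30 ng/kg and its 300 ng/kg mean lies at the vehicle mean; the lower values of ADCYAP1, CBLNL1, TMEM31 and COX11 turn upward with normexp.

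At 30 ng/kg the secretory gene MSMB stood at 0.79 ± 0.36 and the unsaturated probe of KLK3 at 0.97 ± 0.59. Among the collagens, COL5A2 stood at 0.62 ± 0.22, COL1A1 at 0.34 ± 0.41, COL1A2 at -0.17 ± 0.29 and COL6A2 at -0.02 ± 0.48, and MMP2 stood at 0.27 ± 0.29. ITGB4 stood at 0.72 ± 0.24, S100A2 at -0.69 ± 0.57, RBP4 at 0.23 ± 0.64 and NR3C1 at 0.12 ± 0.23. Slide as a fixed block turned RBP4 to -0.092 and NR3C1 to -0.24, and COL1A1, COL6A2, RBP4 and NR3C1 changed sides with 1 array left out. STS was at least 1.54-fold higher. S100A2, with 1 array of 30 ng/kg well above background, turned to 0.66 with normexp, which is 0.37 above its shift.

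limma called 0 probes between 30 ng/kg and vehicle, with a smallest adjusted p of 0.946. At an unadjusted p under 0.05 there were 766 probes, 489 higher and 277 lower, against 758 by chance, and the groups did not overlap at 9.38% of probes against 10% by chance. With 1 array left out the count ranged from 410, without replicate 3 of 30 ng/kg, to 1937, without replicate 2, where 1 probe was called. It was 438 without replicate 1 of 30 ng/kg, 503 without replicate 2 of vehicle and 1138 without its replicate 3. With slide as a fixed block 6 probes were called and 1552 had an unadjusted p under 0.05, with the balance turned (278 higher, 1274 lower). Arrays of slide 2 alone gave 843 (74 and 769), normexp 397 and array weights 3149 (1959 and 1190), so neither the count nor its balance is settled. Adjusted over the list alone, RELB, ITGB4, PECAM1 and LPL were among those that passed in their lists at 30 ng/kg. Over all probes 0 genes passed. RELB and PECAM1 were the only tested genes of their lists, so their p was in effect unadjusted. Over the lists with at least 3 genes, camera called 0 and fry called the secretory list (adjusted p 0.0466), for which camera gave 0.782; 1 of its 3 genes is KLK3 by its saturated probe.

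Genes described above for either dose were also compared between the doses. From 30 to 300 ng/kg, TGM4 stood at 7.83 ± 1.44 (log2 ± SE, n = 3 per group), the unsaturated probe of KLK3 at -2.44 ± 0.59, and MSMB at -1.51 ± 0.36. KRT13 was at least 6.26-fold higher and CRABP2 stood at 4.29 ± 1.24. SMAD7 and TGFBI stood at 1.23 ± 0.26 and 1.66 ± 0.41, while LTBP2 (1.15 ± 0.31) turned to -0.38 with normexp, which is 0.14 above its shift of -0.52. P4HA2, ADAMTS2, SERPINH1 and MMP2 stood at 1.36, 1.44, 0.71 and 0.63, and GREM1, SFRP1 and WNT5A at 2.99, 1.38 and 0.81. COL1A1 stood at 1.20 ± 0.41, COL1A2 at 0.93 ± 0.29 and COL6A2 at -1.59 ± 0.48. PECAM1 stood at -1.31 ± 0.29. Within slide 3, from 1 array of 30 ng/kg, TGM4 stood at 8.83, MSMB at -1.21, SMAD7 at 1.16, TGFBI at 1.77, COL1A1 at 1.63, GREM1 at 3.02 and PECAM1 at -1.56.

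The smallest p between the doses belonged to IRX4, at least 5.93-fold higher at 300 ng/kg, with no 30 ng/kg array well above background. The class I antigen gene HLA-B stood at 4.12 ± 0.61 and ODD, an odd-skipped homolog, at 3.65 ± 0.62 (log2 ± SE, n = 3 per group). DNASE1L3 and VNN2 were at least 8.80- and 8.71-fold higher, and KCNK1 and DNAJA1 stood at 1.51 ± 0.28 and 1.26 ± 0.22. LIPG and HAS2 stood at 2.34 ± 0.29 and 1.69 ± 0.27 but turned to -0.41 and -0.79 with normexp, which is 0.11 above and 0.27 below its shift; each had 1 array of 30 ng/kg well above background. On the lower side, both probes of the gamma-glutamyltransferase gene GGT1 stood at -1.78 and -1.83, and the related GGTL4 at -1.83 ± 0.29. The nitric oxide synthase NOS2A stood at -1.69 ± 0.28, the cation channel TRPM4 at -1.87 ± 0.31, the glutathione transferase GSTT1 at -1.42 ± 0.26 and UNC93B1 at -2.70 ± 0.48. CLTCL1, TTC21A and FARP1 stood between -2.27 and -2.06.

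limma called 0 probes between the doses, with a smallest adjusted p of 0.104. There were 3130 probes at an unadjusted p under 0.05, 1231 higher and 1899 lower; median scaling, which moved the median of all probes by 0.15, gave 1736 higher and 1380 lower, and normexp, which moved it by -0.52, gave 639 higher and 3820 lower. Array weights gave 5950 in all. The count was 1592 without replicate 1 of 30 ng/kg, 1618 without replicate 3 of 300 ng/kg and 1718 without replicate 3 of 30 ng/kg, and at most 4629, without replicate 2 of 30 ng/kg. The groups did not overlap at 3884 probes, 25.6% against 10% by chance. Without replicate 2 of 30 ng/kg limma called 774 probes, without replicate 2 of 300 ng/kg 155, and without replicate 1 of vehicle 1; with array weights it called 2951 and with brightness as a covariate 0, where 528 probes had an unadjusted p under 0.05. Adjusted over the list alone, 4 of 4 TGF-beta genes, 3 of 4 crosslinking genes and 3 of 3 genes in each of the development and stress lists passed. The choice of the names on these same arrays favours such passes. camera with its preset correlation gave TGF-beta signalling an adjusted p of 0.0304 (0.0188 to 0.0654 over the other settings, and 0.202 with an estimated correlation), while fry gave 0.00675. At 30 ng/kg against vehicle the median log2 difference of this list was -0.33 (camera adjusted p 0.390). As computed, the difference between the doses thus includes a part below vehicle at 30 ng/kg. That part was not called, so a share of the lower dose is not shown.

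In the mean of both exposed groups against vehicle, the genes with the smallest p included UBD, CRYAA and LPL, at 1.99 ± 0.29, 2.69 ± 0.48 and 1.38 ± 0.25 (log2 ± SE, n = 6 and 3), where CRYAA had 1 vehicle array well above background. The lipase LIPG and the oxysterol-binding OSBPL3 were higher as well, but no vehicle array was well above background for either, so no size is given. For LIPG 2 of the 3 arrays of 30 ng/kg also lay at the floor, and its difference comes mostly from 300 ng/kg. LSAMP, BFSP1 and SGCA stood at -0.81, -0.97 and -1.08, and ADCYAP1, with no 30 ng/kg array well above background, was lower too. limma called 0 probes, with a smallest adjusted p of 0.628 and 926 at an unadjusted p under 0.05 (550 higher, 376 lower), or 613 to 1604 with 1 array left out. Slide as a fixed block gave 20 calls, of which 19 were lower, and 2215 at an unadjusted p under 0.05 with the balance turned (343 higher, 1872 lower). Array weights gave 2963 and normexp 297.

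The effects of both doses were measured against the same vehicle arrays, which alone makes them correlate. Across probes, the log2 differences at 30 and 300 ng/kg had an r of 0.169, below the 0.500 that simulated unchanged groups gave on average (highest 0.531 of 100 simulations). Their covariance was 0.0527 against 0.110 simulated, a difference of -0.0572. The sign was shared by 53.9% of probes against 66.7% simulated. The simulations drew each probe independently, while the real arrays vary in common over many probes. Their narrow range therefore cannot show that the real values lie below what unchanged groups would give. With slide as a fixed block the r was 0.685, where that design by itself gives 0.728 to unchanged probes, and with normexp it was -0.111. It was 0.395 with brightness as a covariate and lay between -0.0357 and 0.402 with 1 array left out, so its size is not settled. What unchanged probes would give was not computed for these last fits, so their values cannot be set against 0.500. The vehicle group of 3 arrays was too small to be split between the doses.

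The authors' deposited table lists 1502 probes with a 1-way analysis of variance p of at most 0.05 and a fold of at least 1.5 at 1 dose or both. In it, 1261 probes had such a fold at 300 ng/kg (544 higher, 717 lower) and 619 at 30 ng/kg (463 higher, 156 lower). Of the 378 probes at both doses, 187 went the same way. By that table TGM4 was 469-fold higher at 300 ng/kg and 2.05-fold higher at 30 ng/kg. MSMB was 1.65-fold lower at 300 ng/kg and 1.72-fold higher at 30 ng/kg. COL1A1 was 2.91-fold higher and TGFBI 2.07-fold higher at 300 ng/kg, and TGFBI was 1.53-fold lower at 30 ng/kg. Across all 1502 probes of the table, tested or not, the log2 folds computed here and the deposited ones had an r of 0.961 at 300 ng/kg and 0.941 at 30 ng/kg.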

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

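The tests of brightness and slide for the spread among the 300 ng/kg arrays were chosen only after their results were seen; for the test of brightness on the excess of small p-values, the rule that voids it was added after its result was seen.

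Of the 87 named genes, 6 had every 30 ng/kg array on 1 side of all vehicle arrays and every 300 ng/kg array on the other side. All 6 had been named for a small p between the doses, a choice that favours opposite sides. The share of all tested probes with such sides was not computed. For IRX4 every 30 ng/kg array lay at the floor and only 2 vehicle arrays were well above background, so its side at 30 ng/kg rests on floored values. Its difference from 30 to 300 ng/kg, 3.12 on the log2 scale as computed, is given as at least 5.93-fold. The difference was 3.65 for the odd-skipped homolog ODD, -2.27 for CLTCL1, -1.87 for TRPM4, -2.26 for TTC21A and -1.42 for GSTT1. The opposite sides themselves were not tested, and limma's difference between the doses had adjusted p-values of 0.104 to 0.160 for these genes, so none passed.

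More probes than chance had a small p between 300 ng/kg and vehicle, 2357 against 758, and 997 without replicate 3 of 300 ng/kg. The slope of each probe on brightness within the vehicle and 30 ng/kg groups gave a coefficient of 2.25 for this effect. The mark for brightness as the cause, set before the test, was 0.5 or more in every repeat that left out 1 of these arrays. The repeats gave 0.518 to 2.57, so that mark was met. The 0.518, however, came without vehicle replicate 2, where the slopes of both groups covaried at -0.0504. There the slopes of vehicle had an r of -0.238 with the effect and those of 30 ng/kg 0.581. The coefficient has no clear meaning where the slopes are not shared, so by the rule added later the test is void. On the slide of the 300 ng/kg arrays, the single 30 ng/kg array lay -0.0450 of the way along the effect, but single arrays varied by an SD of 0.359, too much to decide. Brightness, slide and the maternal dose therefore cannot be told apart as sources of the excess, and dose stays open as untested against them.

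The 300 ng/kg arrays differed among themselves in the 100 probes farthest from vehicle, with median distances of 3.40, 1.21 and 4.51 for replicates 1, 2 and 3, and replicate 2 was nearest to vehicle in 70 of them. Slide as the cause is argued against, since all 3 arrays lay on 1 slide. The 30 ng/kg array on that slide projected at 0.0831, but it is a single array and decides nothing. Brightness stays open: replicate 2 was brighter than replicate 1 and lay nearer to vehicle by a median of -2.22, but replicate 3 was the brightest and lay farthest, 0.88 beyond replicate 1, and 3 single arrays cannot decide. A larger share of basal or periurethral epithelium in replicates 1 and 3 may contribute, but only 3 of its marker genes were measured: S100A2 was 1.87 and 2.57 above replicate 2, KRT13 -0.73 and 2.20, and ITGB4 0.01 and -0.10. Replicate 2 of 300 ng/kg also correlated more with replicates 2 of 30 ng/kg (0.981) and vehicle (0.978) than with its own group (0.960 and 0.948). The reason was not tested. A difference between the animals stays open, and no test here reached it.

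The authors' table holds 178 probes that were not well above background in any whole group. With the floor set after scaling, 132 of them (74.2%) were under a 1.5-fold difference at both doses, which met the mark set in advance. With the floor before scaling 0 were, but that follows from how the probes were picked, since the authors' raw means carry such a floor. A floor before scaling turns differences in array brightness into fold differences for dim probes. The floor after scaling, however, flattens dim probes whatever put them in the table. The order of floor and scaling is therefore a possible source of their place there, which this test cannot settle. Of the 80 that were well above background on no array, 78 were under 1.5-fold with the floor after scaling. No biological explanation was tested for these probes.

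Other splits of the same arrays were counted against the real groups. For the comparisons of 3 against 3 arrays there are 10 splits, so the share cannot go under 0.05. At an unadjusted p under 0.05 the real split gave 766 probes at 30 ng/kg against vehicle (highest other 3295), 2357 at 300 ng/kg against vehicle (highest other 1347) and 3130 between the doses (highest other 2095). Calls were 0 in each real split, with a highest other of 272, 1 and 0. The split with 272 calls put vehicle replicates 1 and 2 with replicate 2 of 30 ng/kg, so these 6 arrays have a structure that is not the dose; with slide as a fixed block limma called 6 probes.

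For the exposed mean against vehicle, chance was not excluded: 25 of 84 splits gave at least the real 926 probes at an unadjusted p under 0.05 (highest other 4996). The 0 real calls decide nothing, since any of the 84 splits has at least 0 (highest other 2381). The split with 2381 calls set vehicle replicate 3 and replicates 1 and 3 of 30 ng/kg apart from the rest, which points to a structure of the samples. With slide as a fixed block limma called 20 probes. For a difference in any group, 4 of 100 drawn splits into 3 groups, the real one included, gave at least the real 2380 probes (highest other 3533). That share is under the 0.05 set in advance, but it lies close to it and comes from a drawn sample of the splits. Chance is thus not firmly excluded, and brightness and slide are not excluded at all.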

How the results depend on the processing

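The alternatives added after the data were seen were the floors, brightness as a covariate, the lists of at least 3 genes, the unfiltered list test with an estimated correlation and the authors' criteria; the rest were planned. For 156 named gene values, 3639 alternative values were computed. Of these, 3459 kept their direction and stayed short of the threshold, which no named gene had passed to begin with. A further 141 came to pass it in the same direction, and 39, of 22 values, reversed. The genes were chosen on these same arrays, which favours a kept direction.

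Probes called, 0 in each comparison with limma (766, 2357, 3130 and 926 at an unadjusted p under 0.05 for 30 ng/kg, 300 ng/kg, 300 minus 30 ng/kg and the exposed mean), changed as follows. Slide as a fixed block called 6 at 30 ng/kg, 2 between the doses and 20 for the exposed mean. Array weights called 198 at 300 ng/kg and 2951 between the doses, median scaling 3 and the replicate block 1 between the doses, and the floor before scaling 1 at 300 ng/kg. An unadjusted p with a fold of at least 2 gave 259, 1195, 1629 and 239, by its looser construction. Leaving out 1 array gave 0 to 1 at 30 ng/kg, 0 to 271 at 300 ng/kg (271 without its replicate 2), 0 to 774 between the doses (774 without replicate 2 of 30 ng/kg, 155 without replicate 2 of 300 ng/kg, 1 without vehicle replicate 1) and 0 for the exposed mean. With brightness as a covariate 691, 1116, 528 and 1103 probes had an unadjusted p under 0.05 and 0 were called. The correlation of the dose effects moved from 0.169 to 0.685 with slide as a fixed block, to -0.111 with normexp and to 0.395 with brightness as a covariate, and lay between -0.0357 and 0.402 with 1 array left out. The causes were not tested.

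Replicate number as a block moved the counts at an unadjusted p under 0.05 to 923, 2461, 3262 and 1058. The numbers were not taken to pair the animals, since over all 9 pairs of arrays with the same number the deviations from the group mean correlated at -0.256 to 0.543. The 3 pairs of vehicle and 30 ng/kg were all positive, at 0.134, 0.543 and 0.264, a hint from the data. Not every array, however, correlated best with its own number. In the log2 values themselves, replicates 2 of vehicle and 30 ng/kg correlated at 0.984 and those of both doses at 0.981. Those of vehicle and 300 ng/kg correlated at 0.978. These values lay above every pair of the same group (at most 0.975), while pairs numbered 1 or 3 lay between 0.884 and 0.966. What the replicates 2 share was not tested.

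Lists called, 0 of 0 testable, became 1 at 300 ng/kg without a filter, since crosslinking then had 5 genes (adjusted p 0.0347), but 0 with an estimated correlation (0.160). With lists of at least 3 genes fry called 1 at 30 ng/kg, 4 at 300 ng/kg and 3 between the doses, and camera with the preset correlation 1 between the doses, since more lists were then testable; with an estimated correlation camera called 0, and TGF-beta signalling between the doses had an adjusted p of 0.202.

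Named genes that reversed did so mostly with normexp, which moved the median of all probes by 0.29 at 30 ng/kg, -0.22 at 300 ng/kg and -0.52 between the doses; its offset weighs more on dim arrays by construction. At 30 ng/kg ADCYAP1 became 0.55, CBLNL1 0.58, COX11 0.13, S100A2 0.66 and TMEM31 0.63. At 300 ng/kg CTSS became -0.16 and STS -0.49. Between the doses COL5A2 became 0.020, CTSS -0.95, FCER1A -0.48, HAS2 -0.79, LIPG -0.41, LTBP2 -0.38 and S100A2 -0.34. Relative to the shift, 8 of these 14 stayed reversed. Between the doses, median scaling turned COL5A2 to 0.039 and STS to 0.17, quantile scaling STS to 0.17, array weights STS to 0.082, and brightness as a covariate LPL to 0.13 and STS to 0.33. Array weights turned COL6A2 to 0.36 at 30 ng/kg and ITGB4 to -0.014 at 300 ng/kg. Slide as a fixed block turned COL5A2 to -0.23 at 300 ng/kg, and NR3C1 and RBP4 to -0.24 and -0.092 at 30 ng/kg. The arrays of 1 slide give the same 30 ng/kg values by construction. With 1 array left out, COL1A1 at 30 ng/kg ranged from -0.0051 to 0.61, COL6A2 from -0.40 to 0.31, NR3C1 from -0.043 to 0.29 and RBP4 from -0.19 to 0.62, and between the doses COL5A2 ranged from -0.23 to 0.028 and STS from -0.25 to 0.15. The causes of these reversals were not tested beyond the normexp shift.

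Arrays of a single slide gave no value for 300 ng/kg against vehicle, since no slide held both, nor a value of its own for the exposed mean. Signal over background limits LIPG, VNN2, STS and OSBPL3 in vehicle, and IRX4, VNN2, DNASE1L3, KRT13, ADCYAP1, CBLNL1 and TMEM31 at 30 ng/kg, where 0 arrays were well above background.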

Other observations

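With replicate 2 of 300 ng/kg left out, limma called 271 probes between 300 ng/kg and vehicle, 84 of them with a gene symbol and 64 of these higher; the genes below were chosen after their values were seen. They are single genes picked from the 84, not a tested group. The keratin KRT23 stood at 5.15 on the log2 scale, the mucosal glycoprotein DMBT1 at 5.08, the annexin ANXA8 at 4.44, the apical trafficking gene MAL2 at 4.41 and the epithelial transcription factor GRHL3 at 3.05. Replicate 2 by itself stood at 1.19, 1.90, 1.19, 0.92 and 1.31 above the vehicle mean for these genes, the same side with smaller values. The homeobox genes IRX3 and IRX1 stood at 3.16 and 1.96, the vitamin D receptor VDR at 2.90, the cortisol-inactivating enzyme HSD11B2 at 3.15 and the growth factor receptor MET at 1.61.

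Others of the same 84 were picked in the same way. ID1, ID2 and ID3, inhibitors of differentiation induced by BMP, stood at 2.79, 2.01 and 1.92, and the pseudoreceptor BAMBI at 1.71, beside the BMP antagonist GREM1 at 4.08. Replicate 2 stood at 0.73, 0.85, 0.85, 0.56 and 1.60 for ID1, ID2, ID3, BAMBI and GREM1. On the lower side were the renal and urogenital transcription factors SIX2 (-1.88) and EYA1 (-2.02), the muscle phosphorylase PYGM (-1.71), the muscle-associated PDLIM7 (-1.57) and the tachykinin receptor TACR2 (-1.62).

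The authors' criteria, run here as an alternative chosen after the data were seen, gave 1304 of 15160 tested probes with the floor after scaling, of which 1293 are in the authors' table. With the floor before scaling and no filter they gave 1640 of 20217 probes, of which 1492 are in the table. At a p of at most 0.05 alone there were 1982 tested probes with the floor after scaling, where chance gives 758, and 0 remained after Benjamini-Hochberg adjustment in each of the 4 ways they were run.

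Of the 970 tested genes with a symbol, 608 were higher than vehicle at 30 ng/kg (62.7%) and 446 at 300 ng/kg (46.0%). Since the authors' table chose these genes on the same arrays, the shares describe the table and not the genome.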
